A study of Homo sapiens with 16 samples.

How the data were processed

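Bone marrow plasma cells selected on CD138 (syndecan-1) were profiled on 16 single-colour Affymetrix expression arrays, 5 labelled cyclin D1 high and 11 labelled cyclin D1 low. Per the labels, total RNA was extracted with Trizol and converted to biotinylated cRNA. The groups and the replicate names used here come from the labels. The series design speaks of patients with AL amyloidosis, but the labels do not state that each array came from a separate donor, so p-values measure the spread between these arrays. In the labels 1 title carries a mark of a repeat, whose meaning is not stated. All 16 arrays were kept. The highest Spearman correlation of any pair was 0.931, against a median of 0.781 among the 13 arrays without the narrow spread described below. This does not exclude arrays that share a donor, and the p-values treat the arrays as independent.

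The deposited table holds 1 value per probe set and array on a log2 scale. MAS5 is named in the submitters' processing notes, without a version, a scaling target or a step between arrays. The log2 scale was read from the values, which ran from 2.48 to 14.88 with array medians between 4.98 and 5.25. The values were used as deposited, with no pseudocount and no further normalization. No Affymetrix control probe sets were used here, so the RNA integrity ratio planned before the data were examined was not computed. The number of arrays limits the precision, and background intensities were not used here.

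Of 22215 probe sets, 19064 had 1 gene symbol in the platform annotation, 1043 had several and 2108 were not listed there. Entrez identifiers of 19052 of the 1-symbol probe sets matched the gene table of the GRCh38.p14 assembly, and 0 symbols needed updating. That table served for names and neighbours only, and no coordinates are printed because the files name no build. XIST, TSIX and Y-linked genes were left out, with 52 probe sets. Each gene was represented by its probe set of highest mean, which left 11939 genes. Genes above the array median in at least 5 arrays were tested, which left 7802.

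Differences (high minus low) were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), over all 16 arrays and without covariates. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Exact two-sided permutation tests over all 4368 splits of 16 arrays into 5 and 11 were run beside it, and the smallest p these allow is 0.00022894. A set of 24 gene lists covering processes and cell types was fixed before the data were examined, with CCND1 itself removed. Lists were tested with limma's camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry asks whether its genes move one way on balance. Counts of members "adjusted over the list alone" apply Benjamini-Hochberg within the list.

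The genes named in the text follow a rule also written before the data were examined. It takes a fixed set of cyclin, plasma cell, B cell and survival genes, all genes past the threshold, up to 6 per direction of smallest p where fewer pass, and up to 2 members of smallest p from each list. Genes named outside that rule are said to be so. Immunoglobulin genes are given by group, not by array. Not every gene of the fixed set is reported here.

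Sample titles come in 2 written forms, which may mark separate array runs and were treated as a possible batch. Form 1 held 4 high and 3 low arrays, and form 2 held 1 high and 8 low (Fisher's exact p = 0.106, two-sided). The comparison of the groups over the tested genes and the fixed lists was refitted with title form as a term and within each form, which leaves out genes under the filter, the probe set of several symbols and the other members of the amino acid response within each form. Other alternatives were pseudocounts of 1% and 50% of the median linear value, quantile normalization, centring on the 75th percentile, other filters, the mean of all probe sets of a gene, array weights, other variance models and leaving out each array in turn. The fit was tested on simulated data for 5 against 11 arrays and 7802 genes, with 50 genes changed at each size. It recovered 24% of genes changed by 1 on the log2 scale, 68% of those changed by 2, and 100% of those changed by 4 or by 6, with 8 false calls among 154. These simulated genes varied independently and shared no structure of the arrays, so the rates need not hold for the real data. There IGHD, at a difference of -4.20, missed the threshold (limma adjusted p = 0.0899). With independent genes and 1 of 24 lists shifted by 0.8, camera called 2 lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.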

Results

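AL amyloidosis is a disease in which a plasma cell clone secretes an immunoglobulin light chain that deposits in organs as amyloid. CD138-selected bone marrow plasma cells from patients were compared by their level of cyclin D1, a regulator of entry into the cell cycle encoded by CCND1. There were 5 cyclin D1 high arrays and 11 cyclin D1 low arrays. All values below are log2 probe set values, given as mean ± SD, and differences are high minus low. Where a group mean lies below the array medians (4.98 to 5.25), the size of a difference is not well measured.

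CCND1 was higher in the high group. It measured 11.17 ± 0.63 (SD, n = 5) in the high arrays and 4.38 ± 1.01 (SD, n = 11) in the low arrays, a difference of 6.79 (SE 0.46, limma adjusted p = 9.79e-08). All 5 high arrays lay above all 11 low arrays, whose highest value was 7.08 (exact permutation p = 0.00022894, the smallest these splits allow). The low mean lay below the array medians, and the difference was 5.88 with a pseudocount of 50% of the median. A second CCND1 probe set differed by 6.44. The groups were defined by cyclin D1, so this checks the labels and is not independent evidence. Within title form 2, where 1 high array faced 8 low arrays, the difference was 6.71 at a limma adjusted p of 0.0702, and with the stricter filter CCND1 itself was not tested.

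The other D cyclins were not higher in the high group. CCND2, which drives the same step of the cell cycle, measured 4.41 ± 0.58 (SD, n = 5) in the high arrays and 7.0 ± 2.26 (SD, n = 11) in the low arrays. Its difference of -2.59 (SE 0.92) had an exact permutation p of 0.0275, with 5 of 5 high arrays under the low mean, and missed limma's threshold over all genes (adjusted p = 0.996). The high mean lay below the array medians, so the size is not well measured, and it was -2.08 with a pseudocount of 50% of the median. The difference was -1.54 with title form as a term, -1.20 within title form 1 and -2.19 within title form 2. In the low arrays CCND2 was widely spread, between 9.16 and 10.6 in 3 of them and between 3.66 and 8.05 in the other 8. Those 3 also had the highest MAF of the low arrays, and a difference without them was not computed. CCND3 measured 7.28 ± 0.39 (SD, n = 5) and 7.95 ± 1.06 (SD, n = 11), a difference of -0.68 (exact permutation p = 0.20). CCNE1, which encodes cyclin E1, differed by -1.44 (exact permutation p = 0.0403, limma adjusted p = 0.996). Of the 14 measured members of the cyclin D and G1 list, 6 were higher and 8 lower, with a median of -0.17 (camera adjusted p = 0.653) and 0 members past the threshold adjusted over the list alone. The 11q13 neighbours of CCND1 were not higher either. Of 6 measured, 2 were higher and 4 lower (median -0.29, camera adjusted p = 0.441, 0 past the threshold adjusted over the list alone), with CPT1A at -0.54 and PPFIA1 at -0.50.

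**Figure D1:**
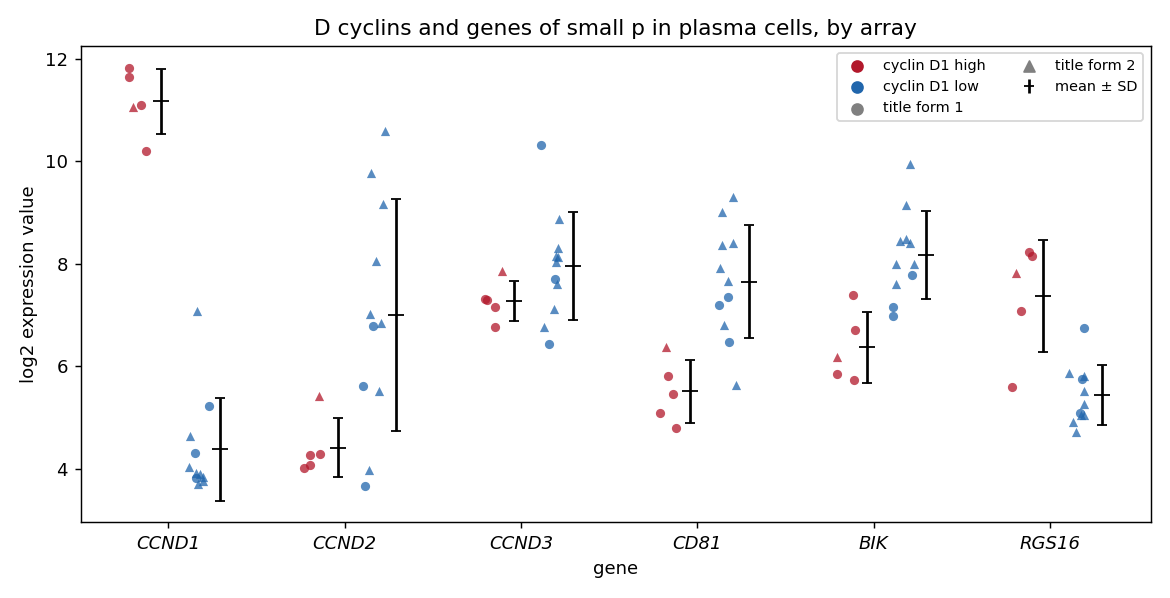
Log2 expression value of 6 genes (vertical axis) in each array, in red for the cyclin D1 high group (n = 5) and blue for the low group (n = 11), with circles for title form 1, triangles for title form 2 and black bars for mean ± SD. High arrays lie between 10.21 and 11.83 for CCND1 and between 4.01 and 5.42 for CCND2, and low arrays between 3.69 and 7.08 and between 3.66 and 10.6.

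Over the 7802 genes tested, CCND1 was the 1 gene past limma's threshold, and 0 genes were lower. At an unadjusted limma p under 0.05 there were 330 genes, 151 higher and 179 lower, against 390.1 expected by chance. Exact permutation tests gave 303 genes under 0.05 and 0 after adjustment. The groups did not overlap for 5 genes (CCND1, TRADD, GPAA1, KLHL20 and IGHD), against 3.57 expected by chance, and TRADD, GPAA1 and KLHL20 were named after their values were seen. A second gene passed without high replicate 1 (RGS16, adjusted p = 0.00616), without high replicate 2 (SMAD1, adjusted p = 0.0189) or without low replicate 3 (IGHD, adjusted p = 0.000955). With array weights 43 genes passed, among them IGHD (adjusted p = 0.00219) and BIK, SMAD1, IER3, RGS16, KCNK12, CD81, BMS1P20, BCL2L1, CDK2AP2, P2RX1, JCHAIN and RNF130 (adjusted p from 0.0116 to 0.0466). Within title form 2, where 1 high array faced 8 low arrays, 5 genes passed. IGHD also passed without the 5 arrays of lowest correlation with the others (adjusted p = 0.0409, BIK at the same value) and with the erythroid marker level as a term (adjusted p = 0.0201, IGLL5 at the same value), both alternatives chosen after the data were seen.

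Genes of smallest p included signalling, surface and survival genes, and all of those named here other than CCND1 missed the limma threshold over all 16 arrays. RGS16, a regulator of G protein signalling, measured 7.38 ± 1.09 (SD, n = 5) and 5.43 ± 0.58 (SD, n = 11), a difference of 1.95 (limma adjusted p = 0.234) with 5 of 5 high arrays over the low mean. CDK2AP2 differed by 1.67, HOOK1 by 1.65, P2RX1, an ATP-gated ion channel, by 1.98, KCNK12, a potassium channel gene, by 2.06 and SMAD1, a BMP signal transducer, by 1.91. Limma adjusted p for these 5 lay between 0.366 and 0.628, and within title form 2 SMAD1 turned to -0.62, while KCNK12 was 0.0575 and HOOK1 0.245. In the other direction CD81, a tetraspanin of the B cell coreceptor, measured 5.50 ± 0.62 (SD, n = 5) and 7.65 ± 1.10 (SD, n = 11), a difference of -2.14 (limma adjusted p = 0.539) with 5 of 5 high arrays under the low mean. BIK, a pro-apoptotic BCL2 family gene, differed by -1.81, CSF2RB, the common beta chain of cytokine receptors, by -2.85, the pseudogene BMS1P20 by -2.14 and RNF130 by -1.61. A second BMS1P20 probe set, near the array medians, differed by -0.26, and whether the first measures another transcript was not tested. Title form as a term moved CSF2RB to -1.63, and BIK was -0.89 and RNF130 -0.49 within title form 1.

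Immunoglobulin genes were lower in the high group as a list. Of 10 measured, 9 were lower, with a median of -0.94 and quartiles of -1.60 and -0.88 (camera adjusted p = 3.38e-08, and adjusted p = 0.110 with an estimated correlation). Of the 10 members 8 passed adjusted over the list alone, 7 of them lower, while 0 passed over all genes. IGHD, the heavy chain constant gene of IgD, measured 4.96 ± 0.46 (SD, n = 5) and 9.16 ± 1.78 (SD, n = 11), a difference of -4.20 (SE 0.75, limma adjusted p = 0.0899, exact permutation p = 0.00022894). The high mean lay below the array medians, so the size is not well measured, and it was -3.65 with a pseudocount of 50% of the median (limma adjusted p = 0.167). The other probe sets of IGHD differed by -1.34, -1.44 and -0.09, and the mean of all its probe sets by -1.77 (limma adjusted p = 0.461). IGLL5, which overlaps the lambda light chain constant region, differed by -2.97 (exact permutation p = 0.00733). JCHAIN, which joins polymeric immunoglobulins, went the other way, at 12.83 ± 0.36 (SD, n = 5) and 11.42 ± 1.04 (SD, n = 11) (difference 1.41, exact permutation p = 0.0114, limma adjusted p = 0.996). The list median was -1.13 with title form as a term, -1.25 within title form 1 and -1.94 within title form 2, where 1 high array faced 8 low arrays. Probe sets of immunoglobulin genes share sequence, and each clone expresses its own chains, so the members are not independent. IGLL5 and, outside the naming rule, IGLC1, IGLJ3, IGLL3P and IGLV1-44 are lambda or lambda-like members of the list. Outside the naming rule, IGLC1 measured 13.76 ± 1.30 (SD, n = 5) and 14.7 ± 0.13 (SD, n = 11). IGLV1-44 measured 12.89 ± 1.28 (SD, n = 5) and 13.78 ± 0.09 (SD, n = 11). The spread of IGLC1 and IGLV1-44 was wide in the high arrays only. Within title form 2, with its 1 high array, they differed by -2.28 and -2.225. In the low arrays IGLC1 lay near the highest value of any array (14.88), so the size of its difference is not well measured.

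Genes of the endoplasmic reticulum and secretion, which fold and export antibody, were higher in the high group as a list. Of 35 measured, 32 were higher, with a median of 0.48 (camera adjusted p = 6.42e-08, and adjusted p = 0.465 with an estimated correlation) and 0 past the threshold adjusted over the list alone. MANF, a stress-induced secreted factor, measured 11.42 ± 1.11 (SD, n = 5) and 10.22 ± 0.84 (SD, n = 11), and the disulfide isomerase PDIA6 measured 11.73 ± 0.63 (SD, n = 5) and 10.59 ± 1.07 (SD, n = 11). The list median was 0.81 without high replicate 3 and 0.22 without high replicate 4. It was 0.57 with title form as a term, 0.73 within title form 1 and 0.33 within title form 2, where 1 high array faced 8 low arrays and the call ended (camera adjusted p = 0.0638). Erythroid, monocyte and granulocyte markers were lower in the same high arrays (medians -0.83, -1.06 and -0.82). The endoplasmic reticulum median was 0.39 with the erythroid marker level as a term (camera adjusted p = 0.000296). It was 0.56 with the monocyte marker level as a term (camera adjusted p = 3.58e-09), both terms chosen after the data were seen. The list stayed higher and the call was kept at the preset correlation. Without these terms the list did not pass with an estimated correlation (adjusted p = 0.465), and no such value is given with them. The kept call can therefore not tell whether erythroid or monocyte cells carry part of the difference. The granulocyte marker level was not used as a term.

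Proteasome, plasma cell identity and interferon response genes were also higher as lists, by smaller amounts. Of 32 proteasome genes 21 were higher (median 0.16, camera adjusted p = 0.0322, and adjusted p = 0.790 with an estimated correlation), among them the regulatory subunits PSMD3 at 1.0 and PSMD8 at 1.08. Of 19 plasma cell identity genes 13 were higher (median 0.21, camera adjusted p = 0.0373, and adjusted p = 0.742 with an estimated correlation), among them SSR4, of the translocon-associated complex, at 0.62. Of 24 interferon response genes 18 were higher (median 0.27, camera adjusted p = 0.0322, and adjusted p = 0.742 with an estimated correlation), with OASL at 0.41 and LY6E at 0.57. In all 3 lists 0 members passed adjusted over the list alone. The proteasome call ended without any 1 of high replicates 1, 4 and 5 and low replicates 6 and 8 (adjusted p from 0.0699 to 0.917, with a median of -0.15 without high replicate 4). The interferon call ended without any 1 of high replicates 1, 3 and 4 and low replicates 3, 5, 6, 8 and 9 (adjusted p from 0.0521 to 0.436), and the identity call without any 1 of high replicates 2, 4 and 5 and low replicates 3, 6 and 8 (adjusted p from 0.0561 to 0.288). The interferon call also ended with no low-value filter (median 0.22, adjusted p = 0.123) and with array weights, where its median was -0.088 (adjusted p = 0.874), as did the proteasome (0.072, adjusted p = 0.321) and identity (0.17, adjusted p = 0.364) calls. With the erythroid marker level as a term, chosen after the data were seen, the identity median was -0.10 (adjusted p = 0.816) and the interferon median 0.079 (adjusted p = 0.627), and the interferon median was 0.19 with the monocyte term (adjusted p = 0.105). All 3 calls ended without the 5 arrays of lowest correlation (adjusted p from 0.210 to 0.837). With title form as a term the interferon and identity calls ended, while the proteasome median was 0.41 with that term, 0.69 within title form 1 and -0.14 within title form 2.

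Proliferation genes were lower in the high group as a list, together with markers of erythroid, monocyte and granulocyte cells. Of 29 proliferation genes 28 were lower (median -0.83, camera adjusted p = 8.33e-09, and adjusted p = 0.465 with an estimated correlation). Among them CCNA2, or cyclin A2, measured 4.38 ± 0.26 (SD, n = 5) and 5.21 ± 0.66 (SD, n = 11), and the spindle gene TPX2 differed by -0.95. All 11 erythroid markers were lower (median -0.83, camera adjusted p = 0.000471, and adjusted p = 0.465 with an estimated correlation), with the carbonic anhydrase gene CA1 at -2.06 and the delta globin gene HBD at -1.74. Of 19 monocyte and macrophage markers 18 were lower (median -1.06, camera adjusted p = 3.46e-06, and adjusted p = 0.465 with an estimated correlation), with S100A12 at -2.20 and MS4A6A at -1.51. Of 6 neutrophil and granulocyte precursor markers 5 were lower (median -0.82, camera adjusted p = 0.000553, and adjusted p = 0.362 with an estimated correlation), with myeloperoxidase, MPO, at -1.96 and RNASE2 at -1.91. In these 4 lists 0 members passed adjusted over the list alone. The proliferation median was -0.17 with title form as a term (camera adjusted p = 0.162), 0.38 within title form 1 and -1.03 within title form 2. Corresponding medians were -0.36, -0.09 and -0.89 for erythroid, -0.11, -0.13 and -0.20 for monocyte and -0.64, -0.28 and -1.56 for granulocyte markers, and the monocyte call ended with the term. In title form 1 high replicate 1 stood apart, with a mean proliferation level of 7.11. The other high arrays of that form lay between 5.09 and 5.31 and its low arrays between 5.19 and 5.36. Within either title form alone the erythroid, monocyte and granulocyte calls ended (adjusted p from 0.0543 to 0.746). The granulocyte median depended on the filter, at -0.17 with no low-value filter, -1.53 with the stricter filter and -0.50 with the mean of all probe sets of a gene, and the monocyte median was -0.69 with that mean, all still past the threshold.

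**Figure D2:**
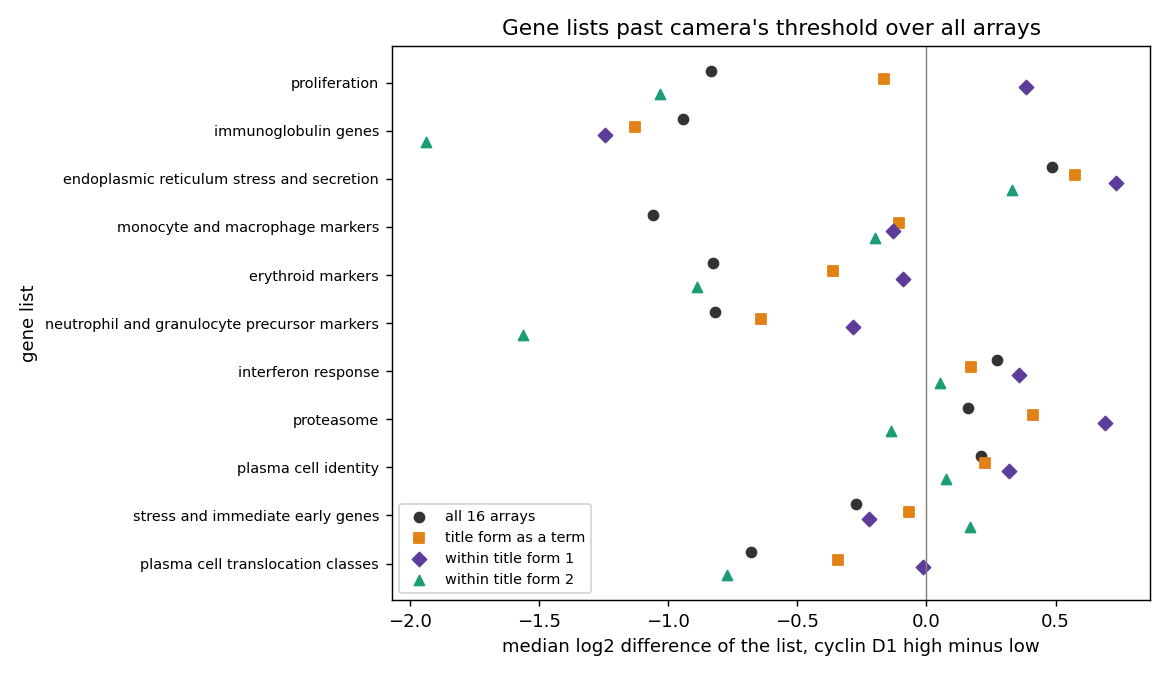
Median log2 difference (horizontal axis, high minus low) of the 11 gene lists past camera's threshold (vertical axis), over all 16 arrays, with title form as a term, and within each title form. The immunoglobulin median lies between -1.94 and -0.94 in the 4 fits, and the proliferation median runs from -1.03 to 0.38. The -1.94 and -1.03 are from title form 2, where 1 high array faced 8 low arrays.

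Stress genes and genes of other translocation classes were lower as lists, near the threshold. Of 23 stress and immediate early genes 16 were lower (median -0.27, camera adjusted p = 0.0438, and adjusted p = 0.790 with an estimated correlation), with IER3 at -2.05 and MYC at -1.46. Of 12 genes that mark other plasma cell translocations 9 were lower (median -0.68, camera adjusted p = 0.0443, and adjusted p = 0.465 with an estimated correlation), CCND2 and MYC having the smallest p. Members past the threshold adjusted over the list alone numbered 0 in both. The transcription factor gene MAF measured 5.15 ± 1.08 (SD, n = 5) and 6.62 ± 2.60 (SD, n = 11), a difference of -1.48 (exact permutation p = 0.317), and ITGB7 differed by -0.36, NSD2 by -0.17 and FGFR3, which was under the filter, by -0.17. MAF lay between 10.25 and 11.21 in 3 low arrays and between 4.36 and 5.89 in the other 8. Those 3 also had the highest CCND2 and ITGB7 of the low arrays. The stress call ended without any 1 of high replicates 3 and 5 and low replicates 1, 4, 7, 8, 9, 10 and 11 (adjusted p from 0.0521 to 0.404). The translocation call ended without any 1 of high replicates 2, 4 and 5 and low replicates 1, 4, 5, 6, 8 and 10 (adjusted p from 0.0521 to 0.207), and both ended with title form as a term. The translocation call also ended with quantile normalization (median -0.61, adjusted p = 0.0571), the stricter filter (-0.36, adjusted p = 0.255) and array weights (-0.78, adjusted p = 0.114), and the stress call with the mean of all probe sets of a gene (-0.17, adjusted p = 0.125), while its median was -0.56 with array weights (adjusted p = 0.00114). With the monocyte marker level as a term, chosen after the data were seen, both ended (stress -0.070, adjusted p = 0.720, and translocation -0.18, adjusted p = 0.227). Without the 5 arrays of lowest correlation the translocation call ended (-1.06, adjusted p = 0.0985).

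B cell genes and survival genes did not differ between the groups as lists. Of 23 B cell genes 11 were higher and 12 lower (median -0.03, camera in the higher direction, adjusted p = 0.937, 0 past the threshold adjusted over the list alone), with MS4A1, or CD20, at 4.95 ± 1.24 (SD, n = 5) and 5.03 ± 0.72 (SD, n = 11), CD79A at 0.37, PAX5 at 0.18, VPREB3 at -0.35, CD79B at 1.12 and BANK1 at 1.41. The memory marker CD27 differed by -1.30 (exact permutation p = 0.0927), and the plasma cell markers SDC1, which encodes CD138, by -0.08 and TNFRSF17, which encodes BCMA, by 0.43. Of 16 BCL2 family genes 7 were higher and 9 lower (median -0.01, camera adjusted p = 0.441), and BIK was the 1 member past the threshold adjusted over the list alone. The anti-apoptotic BCL2L1 differed by -0.98 (exact permutation p = 0.0467, limma adjusted p = 0.996), BCL2 by 1.19 and MCL1 by -0.03. In the adhesion and homing list (28 measured, median -0.04, mean 0.03, camera adjusted p = 0.937, and 0.31 with adjusted p = 0.0387 with the monocyte marker level as a term) CD81 was the 1 member past the threshold adjusted over the list alone, and ALCAM differed by 1.34 and NCAM1, which encodes CD56, by -0.13.

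Other lists did not pass over all 16 arrays. T and NK cell markers had a median of -0.25 (camera adjusted p = 0.102, and adjusted p = 0.790 with an estimated correlation), with GZMA at -1.72 and GZMB at -1.06. They passed as lower in 7 alternatives, namely within title form 1 (-0.29, adjusted p = 0.0174), without the 3 narrow arrays described below (-0.34, adjusted p = 0.0405) and without any 1 of high replicates 2 and 3 and low replicates 2, 9 and 11 (adjusted p from 0.000800 to 0.0255). Oxidative phosphorylation genes had a median of -0.09 (adjusted p = 0.325), with NDUFA6 at -0.77 and CYCS at -0.57, and turned to 0.19 with title form as a term (adjusted p = 0.0130) and 0.62 within title form 1 (adjusted p = 2.57e-05). They passed as lower without any 1 of high replicate 4 and low replicates 6 and 8 (adjusted p from 0.0206 to 0.0271). Within title form 2, where 1 high array faced 8 low arrays, their median was -0.37. With an estimated correlation their camera adjusted p over all 16 arrays was 0.959. Amyloid-associated protein genes had a median of -0.13 (adjusted p = 0.340), with LYZ at -2.09 and SERPINA1 at -1.06, both of which are also in the monocyte and macrophage list. Platelet and megakaryocyte markers had a median of -0.11 (adjusted p = 0.515), with F13A1 at -0.93 and PF4 at -0.40. NF-kappaB pathway genes had a median of 0.15 and a mean of -0.09 (adjusted p = 0.937), with ICAM1 at -0.63. Ribosomal protein genes had a median of 0.01 (adjusted p = 0.937), with RPLP2 at -0.56 and RPL35 at 0.29. B cell precursor markers had a median of -0.17 and a mean of 0.03 (adjusted p = 0.937), with SPINK2 at 1.06 and LEF1 at -0.73. Stromal and fat cell markers had a median of 0.01 and a mean of -0.07 (adjusted p = 0.937), with COL6A1 at -0.49 and FN1 at 0.18. Without high replicate 3 the amyloid-associated (-0.25, adjusted p = 0.0375) and platelet (-0.32, adjusted p = 0.0437) lists passed as lower and the ribosomal list as higher (0.17, adjusted p = 0.0261). In these 8 lists 0 members passed adjusted over the list alone.

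Of the 33 named genes with several probe sets, 17 had probe sets of opposite sign. They were BCL2, BCL2L1, CA1, COL6A1, CPT1A, FGFR3, FN1, ICAM1, LEF1, MAF, MCL1, MS4A1, NCAM1, PPFIA1, RNF130, SERPINA1 and SMAD1. With the mean of all probe sets of a gene, IGLL5 differed by -1.70, BMS1P20 by -1.20, CA1 by -0.99, RNF130 by -0.69, SERPINA1 by -0.61, LEF1 by -0.17, PPFIA1 by -0.025 and BCL2 by 0.28.

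Arrays of the 2 title forms differed in monocyte and macrophage markers and in proliferation and oxidative phosphorylation genes. Between the 7 arrays of form 1 and the 9 of form 2, 13 genes were higher and 20 lower (limma adjusted p under 0.05), and 7 of these 33 had an unadjusted p under 0.05 for cyclin D1 group. Across genes the title form and group differences, taken from the same 16 arrays, had a Pearson r of 0.656. Since 4 of 5 high arrays were of form 1 and 8 of 11 low arrays of form 2, such an r arises in part by design. The r to be had without any real difference was not computed. Proliferation genes were lower in form 1 (median -1.40, camera adjusted p = 2.70e-10, and adjusted p = 0.906 with an estimated correlation). Monocyte and macrophage markers were also lower in form 1 (median -1.69, camera adjusted p = 4.85e-07, and adjusted p = 0.906 with an estimated correlation), as were oxidative phosphorylation genes (median -0.64, camera adjusted p = 6.33e-06, and adjusted p = 0.906 with an estimated correlation). The count of 33 genes became 0 with cyclin D1 group as a term. It was 0 without high replicate 3 or low replicates 4, 6 or 10 and 456 without high replicate 4. Without low replicates 2, 3, 5 or 11 it lay between 61 and 73, and without high replicate 5 or low replicates 1, 7, 8 or 9 between 5 and 14.

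High replicate 3, low replicate 6 and low replicate 8, all of title form 1, had a narrow spread of values. Their SD lay between 1.57 and 1.67, against 1.87 to 2.12 in the other 13 arrays. Their median Spearman correlation with the other arrays was 0.485, against 0.781 among those 13 arrays and 0.748 among the 3. The highest correlation of any pair of arrays was 0.931, and no pair held identical values. With these 3 arrays left out, an alternative chosen after the data were seen, 1 gene and 7 lists passed. The proliferation, immunoglobulin, endoplasmic reticulum, erythroid, monocyte and granulocyte calls held, and the interferon, proteasome, identity, stress and translocation calls ended, while T and NK cell markers passed.

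**Figure D3:**
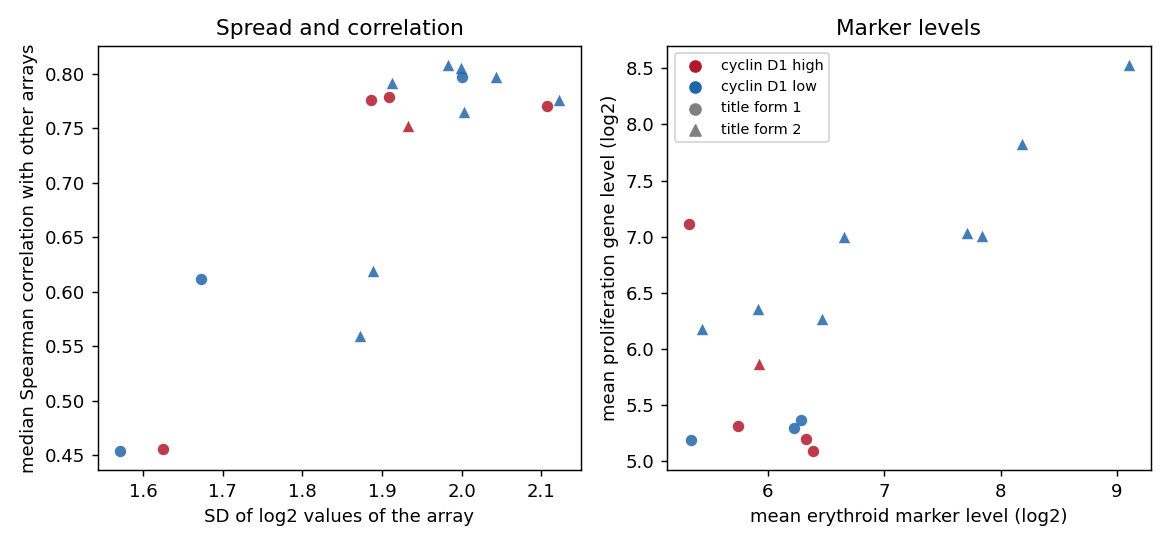
Left, SD of the log2 values of each array (horizontal axis) against its median Spearman correlation with the other arrays (vertical axis). Right, mean log2 level of the erythroid markers (horizontal) against that of the proliferation genes (vertical), in red for cyclin D1 high arrays, blue for low, circles for title form 1 and triangles for form 2. The 3 arrays of SD under 1.7 stand at the left of the first panel, and low replicate 3 has the highest erythroid (9.10) and proliferation (8.53) levels. High replicate 1 has a proliferation level of 7.11 at an erythroid level of 5.32.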

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

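Of the tests on explanations in this part, those of erythroid cells, title form, single probe sets, mature B cells and an even compression were chosen after the results were seen, and the counts over other splits before.

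Within the 5 high arrays, 78 measures were searched for a single array far from the other 4, which chance gives in about 1 of 20 (3.9 expected), and 7 were found. High replicate 2 stood above the other 4 in CCND2 (5.42 against 4.15 ± 0.14), MAF (7.01 against 4.68 ± 0.33) and LEF1 (9.76 against 4.98 ± 0.56). High replicate 3 stood above the others in NCAM1 (5.83 against 4.70 ± 0.11) and OASL (6.80 against 5.77 ± 0.18). It stood below them in NDUFA6 (6.53 against 9.82 ± 0.22) and in its median Spearman correlation with the other arrays (0.456 against 0.769 ± 0.012). Immunoglobulin genes were not searched, and the 11 low arrays are too many for this search.

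Chance can not be excluded for the counts between the groups. Of 100 drawn splits into 5 and 11 arrays, the real one included, 5 gave at least the 1 gene of the real split, and the highest other split gave 485 genes. A split that calls that many points to a structure of the arrays, whose source was not tested. At least the 11 lists of the real split were called in 9 of the 100 splits, with 15 lists in the highest and a median of 7. A list median as far from 0 came in 22 of the 100 for the endoplasmic reticulum, 13 for proliferation and 3 for immunoglobulin genes. For title form, 1 of 100 splits into 7 and 9 arrays gave 33 genes or more, the real one, and the highest other split gave 1. Such a count was rare among the splits, but 100 splits can not exclude chance. The count was 0 without the 3 narrow arrays, all of form 1, and 0 with cyclin D1 group as a term.

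The proliferation list was lower in the high group together with erythroid, monocyte and granulocyte markers. Over the 11 low arrays the mean proliferation level rose with the mean erythroid level (Pearson r = 0.877, permutation p = 0.00038, adjusted 0.00152 over 4 relations, Spearman rho = 0.891, permutation p = 0.00057, adjusted 0.00228), with r = 0.705 without the 2 arrays farthest in erythroid level and r = 0.925 within the 8 low arrays of title form 2. With the erythroid level as a term the list median went from -0.83 (quartiles -1.10 and -0.60) to -0.30 (quartiles -0.48 and -0.07) and the call ended (camera adjusted p = 0.0665), because the difference shrank. Dividing erythroid precursors in the low arrays may therefore carry part of it, although CD138 selection should remove such cells. HBB, the most abundant of those markers, measured 8.73 ± 1.90 (SD, n = 5) and 10.14 ± 2.39 (SD, n = 11). The relation was tested over the low arrays only. High replicate 1 had a proliferation level of 7.11 at an erythroid level of 5.32. The other high arrays had proliferation levels from 5.09 to 5.87. Title form also stays open, since the median was -0.17 (quartiles -0.47 and 0.16) with it as a term, and a lower division rate of cyclin D1 high plasma cells was not tested apart from these.

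For the lower IGHD in the high group, the values argue against 1 faulty probe set and title form as the whole source. The other 2 IGHD probe sets above the array median in 5 arrays or more differed by -1.34 and -1.44 (exact permutation p = 0.0101 and 0.0385), and with title form as a term IGHD differed by -4.44 (SE 0.88). The mean of 6 mature B cell markers was higher in the high group by 0.35 (SE 0.25), where B cells in the low arrays would need it lower. Of these, BANK1 differed by 1.41 and MS4A1 by -0.08. Outside the naming rule FCER2 differed by 0.52, CD22 by 0.21, CXCR5 by 0.19 and BLK by -0.15. The mean rests largely on BANK1, and MS4A1 and CXCR5 lay near the array medians, so it can not tell whether the low arrays held more B cells. Whether the lower signal reached heavy chain constant genes other than IGHD is less clear. IGHM differed by -1.68 (exact permutation p = 0.131) and IGHG1 by -0.87 (exact permutation p = 0.00755), both named outside the rule. No IGHA gene was measured. Cross-hybridisation among heavy chain transcripts was not tested, and a different isotype use of cyclin D1 high clones remains a hypothesis. Of 100 splits, 1 gave IGHD as small a limma p, the real one, and 10 gave some gene other than CCND1 one as small.

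For the 3 arrays with a narrow spread, an even compression of the scale would keep the order of the values, but their median Spearman correlation with the other arrays was 0.485 against 0.781. Title form alone does not set the spread, since 4 of the 7 arrays of form 1 had an SD within the range of form 2 (Fisher's exact p = 0.0625 for the 3 narrow arrays by form, two-sided). RNA quality was not tested, so it may differ in these arrays, and no biological explanation was tested.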

How the results depend on the processing

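Leaving out the 3 narrow arrays or the 5 arrays whose median Spearman correlation was under 0.7, and the erythroid or monocyte marker level as a term, were chosen after the data were seen. The RNA integrity term and its test were not run, since no control probe sets were used here. No paired analysis was possible because the replicate numbers were given in accession order and only name arrays. Where no cause is named, the cause was not tested. The CCND1 difference ran from 5.88 to 7.06 and kept its side of the threshold except within title form 2 (6.71, adjusted p = 0.0702), where 1 high array was assumed to vary like the others. The number of genes past the threshold was 1 in the main setting, 0 with the stricter filter (which removes CCND1), 5 within title form 2, 43 with array weights, 3 without the 5 arrays, 3 with the erythroid term, 2 at an adjusted p under 0.10, and 1 to 2 with 1 array left out. Over all probe sets 3 probe sets passed, 2 of them of CCND1. The number of lists was 11, against 6 with title form as a term, 5 within title form 1, 3 within title form 2, 7 with array weights, 7 without the 3 narrow arrays, 7 without the 5 arrays, 7 with the erythroid term, 0 with an estimated correlation, 0 with fry (smallest adjusted p = 0.0744) and 7 to 13 with 1 array left out (7 without high replicate 5 or low replicate 8). Title form differed in 33 genes, in 0 with cyclin D1 group as a term, 0 without the 3 narrow arrays and 0 to 456 with 1 array left out.

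With title form as a term, signs turned for oxidative phosphorylation (0.19), SERPINA1 (0.015), LEF1 (0.36), PPFIA1 (0.36) and FN1 (-0.11). Within title form 1 they turned for oxidative phosphorylation (0.62), proliferation (0.38), PAX5 (-1.02), HBD (0.30), S100A12 (0.18), PPFIA1 (0.61), CYCS (0.14) and FN1 (-0.10). Within title form 2 they turned for the CCND1 neighbours (0.15), proteasome (-0.14), stress and immediate early genes (0.17), VPREB3 (0.039), CD27 (1.68), TNFRSF17 (-0.66), SMAD1 (-0.62), SERPINA1 (0.67), SPINK2 (-0.21), LEF1 (2.80), LY6E (-0.88), CPT1A (0.33), RPLP2 (0.39), RPL35 (-0.064) and FN1 (-0.14). With array weights the interferon response turned (-0.088). The proteasome median ran from -0.15 to 0.51 with 1 array left out. With the erythroid term, erythroid markers (0.070), plasma cell identity (-0.10) and NSD2 (0.31) turned. With the monocyte term, adhesion and homing (0.31), monocyte and macrophage markers (0.024) and SERPINA1 (0.010) turned. A list tested with its own level as a term is near 0 by construction. Other signs turned only in genes and lists that passed in neither fit, by less than the SE of the gene or the SD of the differences of the list's members. Among them were T and NK cell markers (0.24 within title form 2), B cell precursor markers (0.24 with title form as a term) and cyclin D and G1 regulators (0.16 within title form 1). The immunoglobulin call held in all 33 refits with camera at the preset correlation. With an estimated correlation it did not pass over all 16 arrays (camera adjusted p = 0.110), and its members share sequence.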

Other observations

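The test on MAF and CCND2 was chosen after the values were seen and that on CCND3 before. The amino acid response was taken up from values already seen, and only the criterion for its other members was written before they were tested.

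Among the cyclin D1 low arrays, CCND2 and MAF were high together in 3. MAF, a transcription factor activated by translocation in some plasma cell clones, lay between 10.25 and 11.21 in these 3 arrays and between 4.36 and 5.89 in the other 8. CCND2 lay between 9.16 and 10.6 in the 3 and between 3.66 and 8.05 in the 8. ITGB7, an integrin gene, lay between 11.43 and 11.86 in the 3 and between 5.77 and 11 in the 8, and CCND1 between 3.76 and 3.92 in the 3. No test between these arrays was run, since they were picked by their values.

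A hypothesis that CCND2 follows MAF was tested within the 8 low arrays below the gap. Pearson r was 0.653 (exact permutation p = 0.0764, adjusted 0.153 over 4 relations) and Spearman rho 0.619 (exact permutation p = 0.115, adjusted 0.153), with r = 0.505 without the 2 arrays farthest in MAF, so the relation was not established. MAF in these 8 arrays lay near the array medians (4.98 to 5.25), so the test can not tell whether CCND2 follows MAF. A hypothesis that CCND2 and CCND3 exclude each other was not borne out as a correlation over the 11 low arrays. Pearson r was -0.13 (permutation p = 0.707, adjusted 0.707) and Spearman rho -0.01 (permutation p = 0.988, adjusted 0.988). Pearson r was 0.286 without the 2 arrays farthest in CCND3 and 0.278 within the 8 of title form 2. Both of these leave out low replicate 11, which had the highest CCND3 (10.32) and the lowest CCND2 (3.66) of the low arrays. A correlation can not tell whether the genes exclude each other when a single array is so high in CCND3. A relation of monocyte markers with proliferation was not established in the same family (Pearson r = 0.440, permutation p = 0.175, adjusted 0.233, Spearman rho = 0.564, permutation p = 0.0754, adjusted 0.151), with r = 0.192 without the 2 farthest arrays and -0.08 within the 8 of title form 2.

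Genes of the amino acid response, which cells switch on when amino acids run short or the endoplasmic reticulum is under stress, were noticed among the 43 genes past the threshold with array weights. ATF5, ASS1, PHGDH, TRIB3 and WARS1 were among these, ASNS was added, and all were named after their values were seen. ASS1, of arginine synthesis, measured 8.69 ± 2.35 (SD, n = 5) and 6.09 ± 1.12 (SD, n = 11) (exact permutation p = 0.00893). ATF5 differed by 1.97, asparagine synthetase, ASNS, by 1.90, WARS1 by 1.66, the serine synthesis gene PHGDH by 1.47 and TRIB3 by 1.37, all at a limma adjusted p of 0.996. A hypothesis that the response as a whole is higher in the high group was tested on 31 other measured members. Of these 23 were higher, with a median of 0.41, and 12 of 100 splits gave a median as high, so chance can not be excluded. Camera gave p = 0.000489 at the preset correlation and p = 0.197 with an estimated correlation, 0 members passed adjusted over the list alone, and the median was 0.46 with title form as a term.

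With all 12520 probe sets tested, 1 probe set that the annotation gives 5 symbols was lower in the high group, at 11.95 ± 1.08 (SD, n = 5) and 14.51 ± 0.26 (SD, n = 11) (limma adjusted p = 0.000309, exact permutation p = 0.00022894). In the low arrays it lay near the highest value of any array (14.88), so the size of its difference is not well measured. It was chosen after its values were seen and is not named.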
